A study of Homo sapiens with 8 samples.

How the data were processed

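RNA was measured on 8 arrays in 4 groups of 2. The groups were p53-wild-type (p53-WT) cells, p53-null cells, extracellular vesicles (EVs) from p53-WT cells and EVs from p53-null cells. Per the labels, the material was an oral cavity squamous cell carcinoma line. The labels carry replicate numbers 2 and 3 for p53-WT cells and 1 and 2 for the other groups. They do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which can be technical.

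Each array was a one-colour Agilent custom non-coding RNA array read with Cy3. Per the file headers, the authors' scans were processed with Feature Extraction 11.5.1.1, and the deposited spot intensity is a background-subtracted processed signal on a linear scale. The submitters' processing notes name limma, with no version and no role. The deposited value table held 48035 rows of log2 values, of which 68 were control rows, and its 8 column medians lay between 6.14 and 6.18. The medians were 6.16 on each p53-WT cell array, 6.14 and 6.16 on the p53-null cell arrays, 6.18 and 6.17 on the p53-WT EV arrays, and 6.16 and 6.18 on the p53-null EV arrays. Set against the scanner values, each column of that table had a Pearson correlation across probes of at least 0.993 with normexp-corrected, quantile-normalized signals, and its EV minus cell differences had one of 0.992. The deposited table is therefore on a log2 scale without gene centring and runs in the direction of signal. Its exact steps are not given in the sources used here.

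A probe's value was the mean log2 processed signal over its 3 or 4 spots, after leaving out control spots and spots carrying an outlier flag. No spot was saturated. From each array's values the 75th percentile was subtracted, taken over the 4225 probes well above background on all 8 arrays, since under 50% of probes were detected. A dark spot was one under 1 part in 8 of its probe's median where that median was over 1000. A probe counted as well above background on an array where over 50% of its spots carried that flag. Of 49638 probes, 17378 were well above background on both arrays of at least 1 group and were tested. The number of arrays limits the precision, with 2 per group.

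Probes carry only a transcript accession (14543 accessions, many covered by several probes). Accessions were matched without versions to RefSeq transcripts of the assembly GRCh38.p14, which named 9127 probes with 2454 symbols, and 40511 probes kept their accession. Of the probes with an NM_ accession, 528 had no match. The file headers name an older build for the array, so no coordinates are printed. The files do not say which part or strand of a locus a probe targets, so a value is that of a probe annotated to the gene and need not be its messenger RNA. Probes for MDM2 and the microRNAs of the gene lists could not be named with the table used and are not analysed here.

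All 8 arrays entered 1 limma fit (version 3.58.1, R 4.3.3, with files read by the R package data.table, version 1.17.8) with 1 mean per group, lmFit and eBayes, giving 4 residual degrees of freedom. The eBayes prior had 547 degrees of freedom, so each probe's spread was drawn almost wholly to 1 common to all probes. A p-value here therefore says little about a probe's own spread between its replicates. The contrasts were p53-null minus p53-WT in cells, the same in EVs, EVs minus cells as the mean of both genotypes, and the p53 difference in EVs minus that in cells. The threshold was a two-sided Benjamini-Hochberg adjusted p of 0.05 over the 17378 probes. Of the 26 lists, 12 of microRNAs matched no probe. Gene lists with at least 5 tested members were tested with camera (correlation 0.01, and with an estimated correlation) and fry, with 1 probe per symbol, the one of highest mean log2 signal. The share of probes detected was compared with a two-sided exact permutation test of 4 EV against 4 cell arrays (70 arrangements).

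The tests, the 26 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per contrast, probes with a symbol past the threshold whose groups did not overlap, and of these the 10 of largest change in each direction, 1 probe per symbol. For EVs minus cells the direction also had to be the same in both genotypes. Where none passed, the 5 of smallest p were given as values, and for the difference between EVs and cells in the p53 effect the 10 of smallest adjusted p. Up to 4 members per gene list were added, the past-threshold members of smallest p, or the 2 of highest signal, as values, in a list without any. XIST and Y-linked genes were left out.

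For a probe not well above background on any array of the dimmer group, a fold is given as a bound. It sets the mean log2 value of the brighter group against the mean over the dimmer group's arrays of the higher of the probe's own value and the lowest value among probes well above background. The bound holds only for the reference it is given with, and other scalings can give smaller differences.

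The p53 contrasts each lay within 1 of the 2 slides, while all 4 cell arrays were on slide 1 and all 4 EV arrays on slide 2, which also had separate scans. Alternatives were normexp background correction (offset 50) with quantile or percentile scaling, the percentile over all probes, quantile normalization of the processed signal, the deposited log2 table, other filters on dim probes, each array left out in turn, the replicate number as a block, only the arrays of a comparison, eBayes with a trend and robust prior, and a 2-fold minimum. Normexp used the median spot signal, because the files used here hold no mean signal column. Alternatives chosen after seeing the data were the median over all spots of a probe with flags ignored, median centring over the tested probes, and fits without arrays that stood apart.

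The fit was tested on simulated arrays of 17378 probes with 200 changed probes per contrast. Their noise was Gaussian, independent between probes and of the spread that the fit estimated, without dark spots or an array that stood apart. The rates below therefore hold under the fit's own assumptions and need not be those of the real arrays. For p53 in cells it recovered 4.48% of changes of 1 on the log2 scale, 35.8% of changes of 2 and 90.9% of changes of 3, with 4 false calls. With the spread of the 4 cell arrays alone it recovered 31.3%, 94.0% and 100% of these, with 10 false calls. For p53 in EVs it recovered 1.49%, 52.2% and 92.4%, with 4 false calls. For EVs minus cells it recovered 13.4%, 88.1% and 100%, with 5 false calls. On the real arrays that contrast called 15495 of 17378 probes, far more than 200. The adjusted threshold is then less strict, so these rates for EVs minus cells do not apply to the real contrast. For the difference between the p53 effects the fit recovered 1.49%, 7.46% and 37.9%, with 1 false call.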

Results

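RNA of cells and of the extracellular vesicles (EVs) they release was measured in p53-wild-type (p53-WT) and p53-null samples of isogenic oral cavity squamous carcinoma cells. The array carried 49638 probes and was designed for non-coding RNA. Each of 4 groups had 2 arrays, and the design asks how non-coding RNA levels differ with p53 status. Values below are log2 signals relative to each array's 75th percentile of commonly detected probes. A gene's name stands for a probe annotated to that gene, which need not report its messenger RNA.

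Fewer probes were detected in EVs than in cells, and the EV signal was concentrated on a few probes. Probes well above background made up 34.7% ± 1.29 (SD, n = 4) of all probes on cell arrays and 13.8% ± 2.38 (SD, n = 4) on EV arrays. Every EV array lay below every cell array (exact permutation test, two-sided p = 0.0286, the smallest this design allows). By group, the share was 34.2% ± 2.04 in p53-WT cells, 35.1% ± 0.164 in p53-null cells, 12.8% ± 3.54 in p53-WT EVs and 14.8% ± 0.738 in p53-null EVs (SD, n = 2 each). Replicate 2 of the p53-WT EVs had the lowest share, 10.3%. With probes above the 95th percentile of negative controls counted instead, the shares were 66.7% ± 1.27 in cells and 55.9% ± 2.98 in EVs (SD, n = 4 each).

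The 10 brightest probes held 1.61% ± 0.168 of the summed signal on cell arrays and 31.4% ± 4.50 on EV arrays (SD, n = 4 each), after subtracting each array's median. All 10 on each EV array belonged to 1 transcript, accession DA526557, as did 5 of the 10 on each cell array. Its 26 probes held 2.12% ± 0.191 of the signal in cells and 35.2% ± 4.40 in EVs (SD, n = 4 each), and 2.11% and 29.7% without the subtraction. The 6 probes annotated to MMP24, a membrane-type metalloproteinase, held 0.0383% ± 0.00168 in cells and 0.563% ± 0.0867 in EVs (SD, n = 4 each). DA526557 and MMP24 were taken because their mean share on the EV arrays was the highest of any accession and of any symbol. An exact permutation test gave a two-sided p of 0.0286 for each, the smallest this design allows, which after such a choice adds no support. A share within an array shows unequal change, and of the 26 probes of DA526557 only 1 was called higher and 1 lower in EVs under all 6 scalings of the scanner signals.

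**Figure D1:**
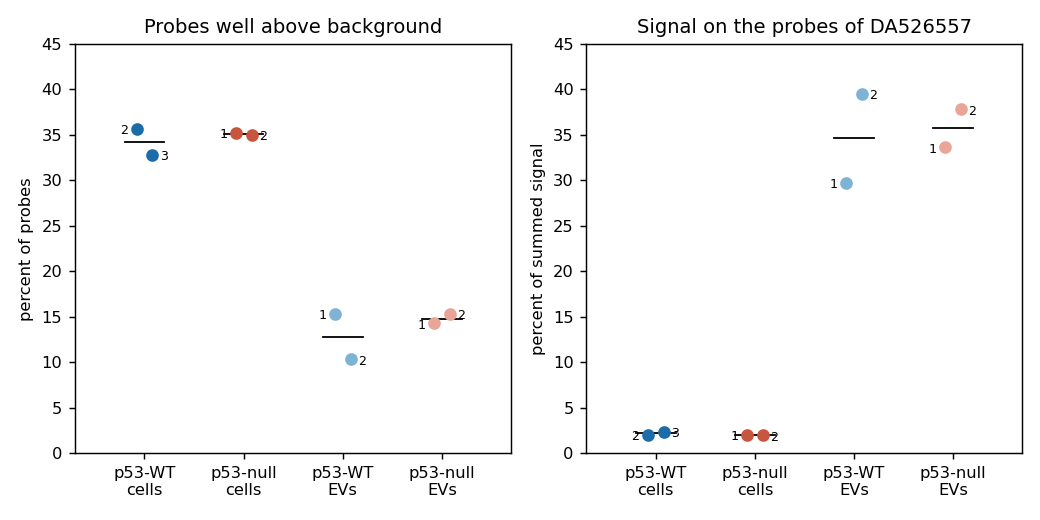
Percent of probes well above background (left) and percent of summed signal on the probes of accession DA526557 (right), by group. Points are arrays with their replicate number and lines are means of 2 arrays. The EV arrays lie between 10.3% and 15.3% of probes detected, against 32.8% to 35.7% for cells, while the share of signal on this transcript lies between 29.7% and 39.5% in EVs and reaches at most 2.41% in cells.

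The 1 probe annotated to CDKN1A, the cell cycle inhibitor induced by p53, was well above background on 0 of 8 arrays. Of 40 known p53 targets, 8 had a probe and 4 were tested, among them TIGAR, RRM2B, TNFRSF10B and CES2. None of the 4 passed the limma threshold between p53-null and p53-WT samples in cells or in EVs, over all probes or adjusted over the list alone. The median p53-null minus p53-WT difference of the 4 was -0.09 in cells. In EVs only CES2 was detected, since the probes of the other 3 were well above background on 0 of 4 EV arrays. For TIGAR, a p53-regulated phosphatase of sugar metabolism, the difference was 0.08 in cells, or -0.35 and 0.51 without p53-null cell replicates 1 and 2. For CES2, a carboxylesterase, it was -0.13 in cells, with its sign turned under 2 of the other 5 scalings and without p53-null cell replicate 1 (0.12). In EVs it was -1.17, or -2.30 and -0.04 without p53-WT EV replicates 1 and 2.

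Probes annotated to STX16, a SNARE protein of Golgi trafficking, and ING4, a chromatin reader, were bright in cells and not well above background on any EV array. STX16 had a mean of 0.65 ± 0.219 in cells and -5.30 ± 0.552 in EVs (SD, n = 4 each). This was at least 20.2-fold lower in EVs with the commonly detected probes as reference and at least 497-fold with all probes as reference (limma adjusted p = 5.88e-39). ING4 had 1.29 ± 0.256 in cells and -4.47 ± 0.860 in EVs (SD, n = 4 each), with bounds of 31.4-fold and 771-fold (limma adjusted p = 8.54e-37). COX18, which inserts a cytochrome oxidase subunit, was at least 21.6-fold lower, and MRPL52, a mitochondrial ribosome protein, at least 19.9-fold. LTBP2 was at least 26.4-fold lower, and TYW5, SSH3, C14orf119 and DCAF10 between 15.8-fold and 21.4-fold. PDP2, a phosphatase that activates pyruvate dehydrogenase, was well above background on 2 of 4 EV arrays and differed by -4.69. All 10 of these differences kept their direction under all 6 scalings, though their size did not hold. The smallest over the scalings was -3.41 for STX16 and -3.81 for ING4. Other probes of the same gene went the other way for TYW5 and LTBP2 (2 of 3 each), ING4 (1 of 3) and DCAF10 (1 of 2).

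Among probes that met the rule for named genes, the largest differences upward in EVs were those of RBM15B, an RNA-binding protein of the RNA methylation machinery, and FBXW8, a ubiquitin ligase subunit. RBM15B had a mean of -0.26 ± 0.554 in EVs and -11.09 ± 0.389 in cells (SD, n = 4 each), and was well above background on 4 of 4 EV arrays and 0 of 4 cell arrays. It was at least 973-fold higher in EVs with the commonly detected probes as reference and at least 39.6-fold with all probes (limma adjusted p = 2.64e-95). For FBXW8 these bounds were 659-fold and 26.8-fold, and for CCDC116 they were 409-fold and 16.7-fold. LMO4, a LIM-only transcription cofactor, had bounds of 247-fold and 10.1-fold, and the cadherin CDH23 had 157-fold and 6.42-fold, each detected on 3 of 4 EV arrays. With normexp and quantile normalization the log2 differences were smaller, 5.29 for RBM15B, 4.50 for FBXW8, 3.74 for CCDC116, 2.95 for LMO4 and 1.69 for CDH23. The remaining 5 were B3GALNT1 and CANT1, enzymes of glycan and nucleotide metabolism, STAC2, the Hippo pathway kinase STK4 and the homeobox factor SIX4. Their differences lay between 7.39 and 8.21, and all 10 kept their direction under all 6 scalings.

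In total 13216 probes were called higher and 2279 lower in EVs by limma, out of 17378. Of the 13216, 7025 were not well above background on any EV array, so that their EV value is background relative to the reference probes. Within genotype the counts were 12665 and 1958 for p53-WT, and 12736 and 2018 for p53-null. Of all tested probes, 85.9% had no overlap between EVs and cells with this reference, where chance gives 2.86% if no shift is common to all probes. Such a shift can set probes apart by itself, so this share does not count the probes that differ. The median tested probe differed by 3.14, and relative to it the RBM15B difference was 7.68 and the STX16 difference -9.10. Higher calls made up 85.3% of calls here, 90.5% with normexp and the same percentile, and 20.8% with the percentile over all probes. They made up 37.8% with normexp and quantile normalization, 38.1% with quantile normalization alone, 46.3% with median centring and 36.4% in the deposited values. Under all 6 scalings 2202 probes of 1153 accessions were higher, 475 of them on no EV array, and 1363 probes of 913 accessions were lower. All EV arrays shared 1 slide and scan and all cell arrays the other, so slide and sample type cannot be told apart.

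**Figure D2:**
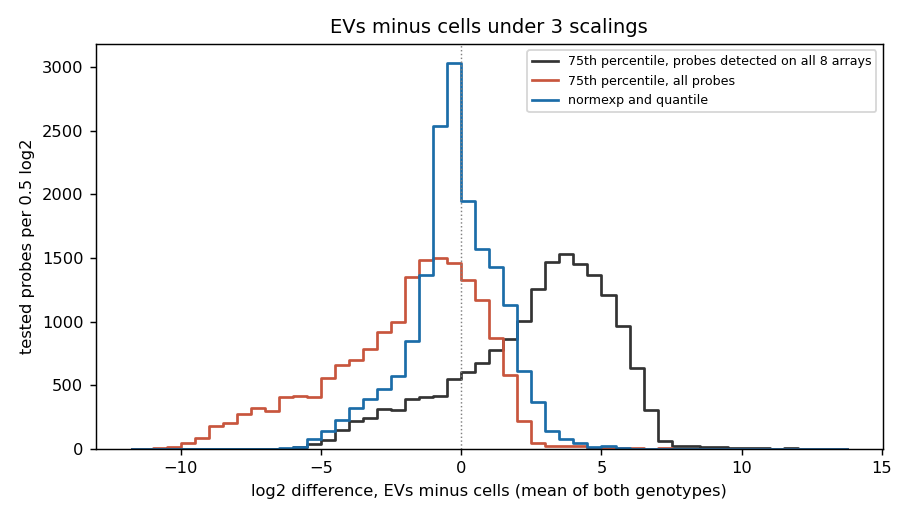
Distribution of the EV minus cell difference (log2, horizontal axis) over 17378 tested probes, as the number of probes in bins of 0.5 (vertical axis), under 3 scalings. The whole distribution shifts with the scaling, from a median of 3.14 with the commonly detected probes as reference to -1.48 with all probes and -0.24 with normexp and quantile normalization.

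Few genes of the preset lists were measured, and 8 of 26 lists had a tested member. In the cell cycle list, 5 of 30 members were tested, and 4 were called higher and 1 lower in EVs by limma, over all probes and adjusted over the list alone. MKI67, a proliferation marker, was well above background on 2 of 4 EV arrays, differed by 6.73 and kept its direction under all 6 scalings. MCM7, a replication helicase subunit, differed by 4.17 and turned its sign under 1 of the other 5 scalings. BIRC5 (2.64) and FOXM1 (2.04) were not well above background on any EV array and turned negative under 4 of the other 5. As the only list with enough members for a set test, it moved on balance upward with the commonly detected probes as reference (limma fry adjusted p = 0.00152, and adjusted p = 4.62e-05 for change in either direction). This direction may depend on the reference, since MCM7, BIRC5 and FOXM1 turned their sign under other scalings. The fry test sets the list against 0 and not against other genes. The median of the list was 2.64, below the 3.14 of all tested probes, so the upward move is not particular to the list. The list did not stand apart from other genes (camera adjusted p = 0.657, and adjusted p = 0.833 with an estimated correlation). Between p53-null and p53-WT samples none of the 5 passed, in cells (camera adjusted p = 0.865, and adjusted p = 0.936 with an estimated correlation) or in EVs (0.267 and 0.603).

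In the neuronal list 3 of 22 members were tested and 2 were called higher in EVs. MAP2, a dendritic microtubule protein, was detected on 4 of 4 EV arrays and differed by 4.77, and by between 0.15 and 4.96 over the scalings. SCN9A, a sodium channel of sensory neurons, was called too (3.52) but was not well above background on any EV array and turned negative under 3 of the other 5 scalings. For TRPV1, a channel of pain-sensing neurons that did not pass, the p53-null minus p53-WT difference was 0.31 in cells and 1.14 in EVs, or 1.90 and 0.38 without p53-WT EV replicates 1 and 2. Both tested members of the axon guidance list were called higher, EPHB2 (4.92), which kept its sign under all 6 scalings, and NRP1 (2.02), which was on no EV array and kept it under 1 of the other 5. The only tested keratinocyte gene, the epithelial cadherin CDH1, was higher (5.47) and kept its sign under all 6 scalings, and the only endothelial gene, VWF (3.49), turned it under 1. With this reference 13216 of all 17378 tested probes were called higher and the median difference was 3.14. The counts of higher members therefore do not set these lists apart from other probes.

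Of the p53 targets 3 were called between EVs and cells. TIGAR was at least 4.19-fold lower in EVs with the commonly detected probes as reference and at least 103-fold with all probes. RRM2B (4.45) and TNFRSF10B (2.33) were called higher but were on no EV array and turned negative under 3 and 4 of the other 5 scalings. RAB27A, which drives vesicle secretion, was at least 1.52-fold and 37.3-fold lower by the same references, and the translation factor EEF1A1 differed by -0.94. Neither was on any EV array, and each turned its sign under 1 of the other 5 scalings. No tested member of any list passed limma between p53-null and p53-WT samples, in cells or in EVs.

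Probes of 8 symbols were called between p53-null and p53-WT cells, and those of 4 symbols also had no overlap between the groups. TMEM115, a Golgi membrane protein, was at -6.89 ± 0.131 in p53-WT cells and at -3.39 ± 0.836 in p53-null cells (SD, n = 2 each), a rise of 3.50 ± 0.587 (SE, limma adjusted p = 8.43e-06). All 4 of its probes differed in that direction and 2 passed. ZNF792, a zinc finger gene, rose by 2.38 (limma adjusted p = 0.0244), and MIB1, a ubiquitin ligase that acts on Notch ligands, by 2.29 (limma adjusted p = 0.0381), being well above background on 1 of 2 p53-WT cell arrays. The anion exchanger SLC26A6 fell by 2.88 (limma adjusted p = 0.00172), with the p53-null arrays at -6.18 ± 2.90 (SD, n = 2). TMEM115 no longer passed without p53-null cell replicate 1 (2.91, limma adjusted p = 0.205) or without either p53-null EV array (limma adjusted p = 0.752). With 1 array left out, ZNF792 and MIB1 passed only where that was a p53-WT EV array, with limma adjusted p of at least 0.176 and 0.382 without any other. With the cell arrays alone all 4 genes passed. With normexp and quantile normalization TMEM115 was at 1.96, ZNF792 at 1.53, MIB1 at 0.66 and SLC26A6 at -1.47, and none of the 4 passed. SLC26A6 was at -0.83 without p53-null cell replicate 1 and also did not pass without either p53-WT cell array or either p53-null EV array. With the median over spots ZNF792 was at 0.57, MIB1 at 2.20 and SLC26A6 at -1.46, and none of these 3 passed, though MIB1 and SLC26A6 did with that median and the cell arrays alone (limma adjusted p = 4.54e-10 and 0.000326). Over all alternatives the adjusted p reached 1 for each of these 4, from a lowest of 8.07e-20 for TMEM115, 1.14e-08 for ZNF792, 4.54e-10 for MIB1 and 7.28e-13 for SLC26A6.

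In all, 13 probes were higher and 39 lower in p53-null cells by limma, from 47 accessions, with 350 of 17378 probes at an unadjusted p under 0.05. Of the 52, 32 had no overlap between the groups, as did 42.3% of all tested probes, where chance gives 33.3%. Of the 39 lower probes, 27 had a dark spot on p53-null cell replicate 1, against 247 of all tested probes, and 242 of its 247 dark spots lay in rows 1 to 200. With the median over all spots of a probe, 6 were higher and 5 lower. There were 0 calls with quantile normalization, the all-probe percentile and the deposited values (285, 1095 and 411 probes at an unadjusted p under 0.05). With only the 4 cell arrays, all on 1 slide, 93 were higher and 177 lower. Leaving out 1 array gave 13 calls without p53-WT cell replicate 2, 13 without p53-WT cell replicate 3, 15 without p53-null cell replicate 1, 312 without either p53-WT EV array and 0 without either p53-null EV array (173 at an unadjusted p under 0.05).

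**Figure D3:**
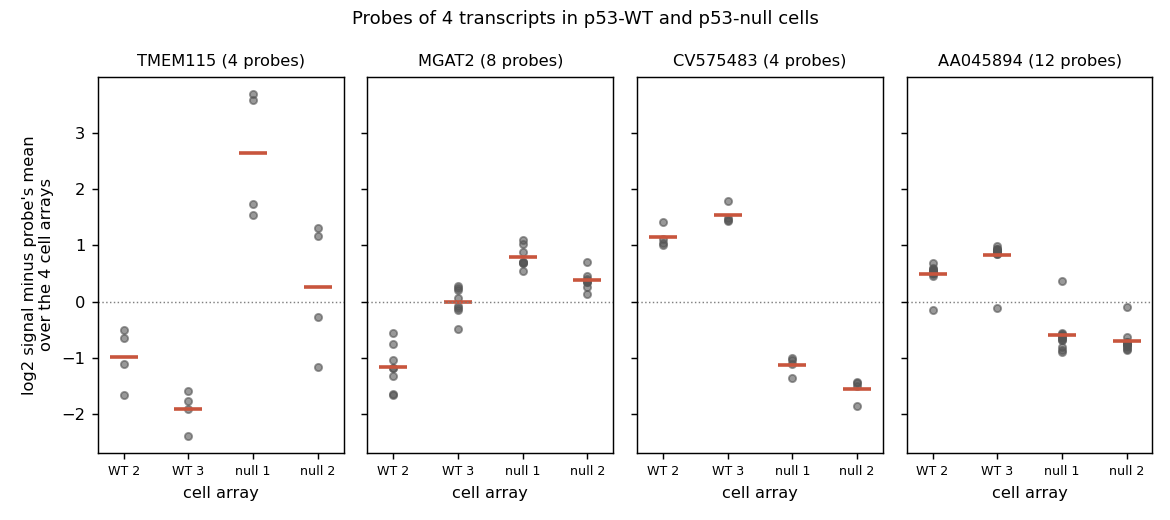
Log2 signal of each probe (median over its spots) minus its mean over the 4 cell arrays (vertical axis), by array, for 4 transcripts, with the mean over probes as a bar. The 4 probes of CV575483 and 11 of the 12 of AA045894 lie lower on both p53-null arrays, MGAT2 lies higher on both, and 2 of the 4 TMEM115 probes are high on p53-null replicate 1 and not on replicate 2.

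No probe with a symbol passed between p53-null and p53-WT EVs. In total 16 probes were higher and 1 lower by limma, from 7 accessions, with 710 probes at an unadjusted p under 0.05. All 8 tested probes of BC067789 were higher in p53-null EVs, by 2.52 to 2.70. Their mean was 2.79 in p53-WT EV replicate 1, -1.50 in p53-WT EV replicate 2, and 2.85 and 3.60 in the p53-null EVs. Of BM918632, 4 of 10 tested probes were higher, by 2.99 to 3.41, with p53-WT EV replicate 2 at -4.42 and the other EV arrays between 1.21 and 1.84. These accessions were named after their values were seen. Among named genes, none of which passed, the differences of smallest p upward were TROAP (2.05), STON1 (1.99), DNAJB2 (1.95), PSMD9 (1.83) and CPT2 (1.83), with limma adjusted p of 0.236 to 0.347. These 5 rested on p53-WT EV replicate 2. Without it they were at 0.24, 0.57, 0.29, 0.74 and 0.44, and without p53-WT EV replicate 1 they passed at 3.85, 3.40, 3.61, 2.92 and 3.22. With a trend and robust prior STON1, DNAJB2, PSMD9 and CPT2 passed, with limma adjusted p of 0.00847 to 0.0338 in a range from 4.62e-14 to 1 over their alternatives. Downward they were HSF4, ANK3, ASTN1, PRX and ANGPTL2, with limma adjusted p of 0.0742 to 1. The probes of HSF4, ANK3, ASTN1 and PRX were not well above background on either p53-null EV array and were so on 1 of 2 p53-WT EV arrays. With the commonly detected probes as reference their values gave bounds of at least 1.77-fold, 3.07-fold, 1.70-fold and 1.85-fold lower. Without p53-null EV replicates 1 and 2 the log2 difference was -2.32 and -0.71 for ASTN1, and -1.80 and -0.98 for PRX. ANGPTL2 differed by -1.36, by -0.26 without p53-WT EV replicate 1 and by -2.46 without p53-WT EV replicate 2, where it passed (limma adjusted p = 0.000175). ASTN1 and PRX passed without p53-WT EV replicate 1 (limma adjusted p = 0.00369 and 0.00339). Without p53-WT EV replicate 2, HSF4 was at 0.11 and ANK3 at 0.43, while without p53-WT EV replicate 1 they passed at -4.89 and -3.66 (limma adjusted p = 1.36e-25 and 2e-14). HSF4 also passed with the median over spots (limma adjusted p = 0.0102). Of the 17 calls 10 had no overlap, as did 20.7% of all tested probes, where chance gives 33.3%.

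Without p53-WT EV replicate 2 there were 201 calls in EVs, and 0 of the 17 were among them. There were 3263 without p53-WT EV replicate 1, 7 without any one of the 4 cell arrays and 0 without p53-null EV replicate 1 or 2 (498 and 51 at an unadjusted p under 0.05). By limma the 4 EV arrays alone, all on 1 slide, gave 0 calls (255 at an unadjusted p under 0.05). Quantile normalization, the all-probe percentile and the deposited values gave 0 too (2088, 1128 and 1707).

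The p53 difference in EVs was not that in cells at 18 probes by limma, 15 of them with a positive difference. TMEM115 was among the 18 (-3.60 ± 0.830, SE, limma adjusted p = 0.0189), but its probe was well above background on 0 of 4 EV arrays, so that no p53 difference in EVs could be read from it. For ZNF792 the p53 difference was 2.38 in cells and -1.25 in EVs, apart by -3.63 ± 0.826 (SE, limma adjusted p = 0.018). With the median over spots ZNF792 was apart by -1.95 and did not pass (limma adjusted p = 0.999). PHLDB3, and BCL9L, a Wnt pathway cofactor, were apart by 4.66 and 4.42 (limma adjusted p = 0.00192 and 0.0112). On p53-null cell replicate 1 the PHLDB3 probe stood at -11.83 and that of BCL9L at -11.80, against -4.40 and -0.81 on replicate 2, and without replicate 1 PHLDB3 was apart by 0.94. Of the 15 probes with a positive difference, 12 had a dark spot on that array and lay there more than 2 below every other cell array. Without that array the 12 were apart by between -1.07 and 2.38, and 0 of them passed, nor did any with the median over spots. TMEM115 and ZNF792 did not pass without either p53-WT cell array, p53-null cell replicate 1 or either p53-null EV array, nor did ZNF792 without p53-null cell replicate 2 (-3.89, limma adjusted p = 0.0651). PHLDB3 did not pass without p53-WT cell replicate 2 (4.61, limma adjusted p = 0.0505), p53-null cell replicate 1 or either p53-null EV array. For each of these 3 the adjusted p reached 1 over the alternatives, from a lowest of 2.93e-18 for PHLDB3, 5.38e-09 for ZNF792 and 4.2e-12 for TMEM115. Probes of BU167807, BM918632 and BC040073 passed too, and were also calls between p53-null and p53-WT EVs. The BU167807 probe was at -2.41 on p53-WT EV replicate 2 and at 1.71 on replicate 1. Those of BM918632 were at -4.41 and -4.45 against 1.22 and 1.06, and that of BC040073 at 0.07 against -3.93. The other genes of smallest p (MIB1, CYP2E1, SLC26A6, STON1, CPT2, TROAP and DNAJB2) did not pass, with limma adjusted p of 0.133 to 0.947. The count was 1726 without p53-WT EV replicate 1 and 1116 without p53-WT EV replicate 2. It was 6 and 33 without replicates 1 and 2 of the p53-null cells, and 0 and 3 without replicates 2 and 3 of the p53-WT cells. It was 0 without p53-null EV replicate 1 or 2 (336 and 49 at an unadjusted p under 0.05).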

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

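What is set against each result in this part was chosen after the results were seen, except the count of other splits of the arrays. The fits with only the cell arrays, without p53-null cell replicate 1 and with the percentile over all probes were alternatives fixed beforehand.

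At 18 probes the p53 difference in EVs was not that in cells. The named ones were PHLDB3 (4.66), BCL9L (4.42), ZNF792 (-3.63) and TMEM115 (-3.60), each as the difference in EVs minus that in cells on the log2 scale. Of the 15 with a positive difference, 12, PHLDB3 and BCL9L among them, had a dark spot on p53-null cell replicate 1, and 0 of the 12 passed with the median over all spots or without that array. ZNF792 was at -1.95 with the median over all spots and did not pass. The probe of TMEM115 was well above background on 0 of 4 EV arrays, so its value shows no p53 difference in EVs. The remaining calls, at BU167807, BM918632 and BC040073, were also calls between p53-null and p53-WT EVs. On these, p53-WT EV replicate 2 stood apart from the other 3 EV arrays.

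Of the 52 calls between p53-null and p53-WT cells, 39 were lower. Of these, 27 had a dark spot on p53-null cell replicate 1, as had 1.42% of tested probes, and 5 of the 39 still passed with the median over all spots. Local damage on that array may lie behind most lower calls. Of the 13 higher calls only 2 had a dark spot, yet 4 still passed with the median, so the loss of calls under it is not particular to dark spots. The spread of the EV arrays also enters this test and may hide calls, since 270 probes passed with the cell arrays alone. A p53 effect stays open for the rest.

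The 17 calls between p53-null and p53-WT EVs may rest on 1 array. In 17 of 17, p53-WT EV replicate 1 lay nearer to the mean of the p53-null EVs than to p53-WT EV replicate 2, as it did for 85.5% of all tested probes. Replicate 2 also had the lowest share of probes detected, 10.3%. Why it stood apart was not tested, and a p53 effect in EVs stays open.

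EVs and cells differed at most tested probes, with 15596 calls in a fit of 2 groups of 4. Of the 35 splits of the 8 arrays into 4 and 4 only 1, the real one, gave as many, and the highest of the others gave 0. Every other split mixes EV and cell arrays, so the difference between them enters its spread and leaves few calls possible. The smallest two-sided p of such a test is 0.0286, so the splits add little to the fit and cannot exclude chance. The direction may be set by the reference probes, since the share of higher calls fell by up to 64.5 percentage points under another scaling. There were 0 slides with both EV and cell arrays, so slide, scan and sample type cannot be told apart. A difference in RNA content between EVs and cells stays open and was not tested apart from these.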

How the results depend on the processing

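Alternatives named as added were chosen after seeing the data. The limma counts were 52 for p53 in cells, 17 for p53 in EVs, 15495 for EVs minus cells and 18 for the difference of the p53 effects. The p53 counts, in that order, were 0, 0 and 0 with quantile normalization (with or without normexp), the percentile over all probes, the deposited values, only probes detected on all arrays and the added median centring. Over all settings with a count of 0, the probes at an unadjusted p under 0.05 numbered 67 to 1095 in cells, 51 to 2088 in EVs and 49 to 1320 for the difference of effects. Normexp with the same percentile gave 31, 8 and 8, and a trend and robust prior 14, 85 and 10. With no filter, and so more probes tested, the counts were 19, 6 and 7, and 47579 for EVs minus cells, and with only probes detected on all arrays, fewer, the last was 3600. The added median over spots gave 11 in cells and 4 for the difference of effects. Only the arrays of the comparison gave 270 in cells and 0 in EVs, and with the median over spots (added) 426 and 0. Without p53-null cell replicate 1 and p53-WT EV replicate 2 together (added) the p53 counts were 115, 741 and 1347. A 2-fold minimum kept all counts within 1.5 times. The gap in detection, -20.9 percentage points, was -10.8 by the 95th percentile of negative controls. No list passed camera under any setting run. Except where the number of probes tested differed, the cause was not tested. The low signal over background on EV arrays limits every EV comparison.

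Leaving out each array in turn gave 0 to 312 calls in cells, 0 to 3263 in EVs, 14964 to 16145 for EVs minus cells and 0 to 1726 for the difference of effects. A group left with 1 array was assumed to vary like the others. For p53 in EVs, HSF4 ranged from -4.89 to 0.11 and ANK3 from -3.66 to 0.43, each turning its sign without p53-WT EV replicate 2, also where p53-null cell replicate 1 was left out too.

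With the replicate number as a block the p53 counts were 6, 7 and 1, and 1 for the EVs alone as 2 pairs. The numbers gave no sign of pairing, since deviations of same-numbered arrays correlated across probes at -0.126 between p53-WT and p53-null EVs, -0.144 between p53-null EVs and cells and -0.02 between p53-WT EVs and p53-null cells. Crossed pairs for the EVs (added) gave 0 calls, with 210 probes at an unadjusted p under 0.05. The slide as a block was not run, since each p53 comparison lies within 1 slide and EVs minus cells lies between slides.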

Other observations

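The fit and accessions of the next paragraph and the tests of clustering and of symbol families were chosen after the data were seen. The tests of chromosomes and of carry-over were written before their results were seen.

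With the 4 cell arrays alone and the median over spots, 214 probes were higher and 212 lower in p53-null cells by limma, from 321 accessions and 57 symbols. The standard error was 0.304 at the strongest probe of every transcript named below. A call therefore followed the size of the difference and says little about how well the replicates of a probe agreed. The median tested probe differed by -0.23 in this fit, which favours lower calls. The 4 probes of CV575483 were lower on both p53-null arrays, with a mean difference of -2.69 ± 0.359 (SD over 4 probes), which is 6.43-fold. For AA045894, 11 of 12 probes were called lower, with a mean of -1.31 ± 0.503 (SD over 12 probes). BC111028 had 7 of 8 probes called lower, with a mean of -1.01 ± 0.0445 (SD over 8 probes). Among named genes, RAB11FIP4, an effector of recycling endosome trafficking, had 4 of 6 probes called lower (mean -1.07), and NFKBIZ, an atypical inhibitor of NF-kappa-B, 2 of 5 (mean -0.89). MGAT2, a Golgi enzyme of N-glycan synthesis, had 5 of 8 called higher (mean 1.17), and all 8 had no overlap between the groups. Of all probes called in this fit 95.5% had no overlap, and the 8 belong to 1 transcript, so this adds no separate support. TMEM115 had 4 of 4 probes called higher (mean 2.90), 3 of them without overlap. Relative to the mean over the cell arrays its probes averaged 2.64 on p53-null cell replicate 1 and 0.26 on replicate 2. The transcripts named here were picked, so they do not show the balance of higher and lower calls. With quantile normalization of the same arrays 53 probes passed, 36 higher and 17 lower, and 52 of the 53 were shared. These held 4 of 4 probes for CV575483, 8 of 12 for AA045894, 3 of 8 for MGAT2, 1 of 4 for TMEM115, and 0 for BC111028, RAB11FIP4 and NFKBIZ. With it the mean difference was -1.65 for CV575483, -0.75 for AA045894, -0.49 for BC111028, -0.53 for RAB11FIP4, -0.40 for NFKBIZ and 1.19 for MGAT2. Without p53-WT cell replicate 2 the MGAT2 mean was 0.59 in place of 1.17.

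The calls gathered on single transcripts. There were 20 accessions with at least 3 calls, 2 of them with calls in both directions, while 1000 random draws of as many tested probes gave a median of 1 and at most 6. This argues against chance at single probes. Probes of a transcript read the same RNA on each array, so a difference between these particular samples may account for it as well as p53, and 2 arrays per group cannot separate these.

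A hypothesis was that a copy number difference between the cell lines sets whole chromosomes apart. By camera with an estimated correlation, 0 of 20 chromosomes passed and 0 had an unadjusted p under 0.05, the smallest p being 0.504. The estimated correlations, 0.228 to 0.589, leave this test little power. The chromosome medians lay between -0.33 and -0.16, around -0.24 over all named genes. Smaller regions were not tested.

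Another hypothesis was that p53 differences in cells carry into EVs. Of 42 accessions called in cells with the fit above and detected in EVs, 45.2% had the same direction in EVs, against a median of 50% and a 95th percentile of 64.3% in 10000 random sets. The share was not above that of random sets, and the spread of the EV arrays limits this test.

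Among 8 symbol families with at least 6 tested genes, none passed a test of its share of genes higher or lower in EVs under all scalings against the other genes (Fisher's exact test, smallest adjusted p = 0.904 of 16 tests).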
